A study of Mus musculus with 4 samples.

How the data were processed

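Whole mouse embryos homozygous for the V1330M allele of Btaf1 were compared with wild-type embryos on 4 two-colour Agilent whole-genome arrays. Each array held RNA from 1 mutant pool and 1 wild-type pool, 300 ng per dye by the labels, from embryos of 3 to 5 somites where possible. The mice were C57BL/6J by FVB/NJ hybrids with 50 to 90% FVB/NJ. The labels describe 2 sets of pools. In the stage_matched set the somite number decided the pairing; in the age_matched set litter mates came first and up to 5 somites of difference were accepted. Each set was hybridised once with the mutant in Cy5 (replicate 1) and once with the dyes exchanged (replicate 2). Both arrays of a set measured the same pair of pools and count as 1 replicate, so n = 2 throughout. The labels give neither the embryos per pool nor whether the sets shared any. They also do not say whether yolk sacs were kept.

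Spot and background intensity per dye came from the scanner, per the file headers, with no normalization in the mean signal and median background columns. The processed intensity columns were background-subtracted, spatially detrended and dye-normalized (linear and lowess) by the scanning software, per the file headers. The log10 ratio column is the log10 of processed Cy5 over processed Cy3, per the file headers. The authors' deposited value table holds that log10 ratio with its sign turned on the dye-exchanged arrays, so that every column is mutant over wild type. It differed from the scanner's column by at most 5e-06, its median was 0 on each array, and all 4 of its columns were assigned, with 0 left over. The labels name Feature Extraction 9.5.3, while the file headers give 10.5.1.1. The submitters' processing notes name ArrayAssist and Excel for analysis, without the steps. All 4 arrays sat on 1 slide with 1 scan, so slide and scan could not differ between groups.

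From the unprocessed intensities, log2 ratios were computed with limma 3.58.1 in R 4.3.3. Spots marked by the software as non-uniform, as population outliers or by hand were left out. Background was corrected with normexp (offset 50). Dye bias that depends on intensity was corrected by loess within each array, with control spots at weight 0. Dye bias of single probes can remain after this step. Arrays were not scaled to each other. The sign was turned on the dye-exchanged arrays, and spots of a probe were averaged. Of 41174 probes, 21940 were tested because they were well above background in the mutant channel on all 4 arrays or in the wild-type channel on all 4; 36 more met this but had a marked spot. The reference gene table (GRCm38.p6) was used for names alone. It named 25097 probes by the accession in the file and 156 by another accession; 6233 kept the file's symbol and 9688 had none. The 19217 tested probes with a symbol stood for 12895 genes, each represented by its brightest tested probe, chosen without regard to the ratio. Probe positions are those of the files (mm9, NCBI37). No annotation of that build was at hand, so exons and untranslated regions are not given.

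Mutant over wild type was tested with limma on the 2 set means (1 residual degree of freedom, moderated with 7.12 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Changes of at least 2-fold and 1.5-fold with 1 sign on all 4 arrays were counted without a test, beside the same count with the sign of 1 set turned. The difference between the sets was tested with limma on the 4 arrays with terms for set and dye. Its error comes from the spread between dye-exchanged arrays (1 residual degree of freedom), which is technical and holds no variation between embryos. Moderation made this error nearly alike across genes, with an SE from 0.175 to 0.193 over the named genes. A call thus follows mainly the size of the difference and not a gene's own spread. Fixed gene lists, 32 in all, were tested with limma's camera (inter-gene correlation preset at 0.01), adjusted over the lists, and again with the correlation estimated. At the preset, the camera p takes its error from the spread over genes and does not measure variation between pools. With an estimated correlation, camera relies on the residual degrees of freedom of the fit, 1 here. Hardly any list could pass that version, so failing it says little about a list whose estimated correlation lay near the preset. The lists covered regulators of TBP, TFIID subunits, Pol I and Pol III machinery, ribosomal proteins, S phase, mitosis, apoptosis genes, p53 targets, heat shock, hypoxia and glycolysis, and the integrated stress and unfolded protein response. They also covered targets of FGF, Wnt, Hedgehog, BMP, retinoic acid and Notch signalling, Hox genes, left-right asymmetry, and sex-linked genes. Tissue lists covered primitive streak and pluripotency, presomitic mesoderm and somite, neural tube and brain, neural crest, gut endoderm and notochord, visceral endoderm and yolk sac, trophoblast, maternal decidua and blood, allantois and extraembryonic mesoderm, primitive erythroid, endothelial, and cardiac genes. Genes within 20 Mb of Btaf1 were compared with all other placed genes by two-sided Fisher's exact test, since mutants carry C57BL/6J sequence there. Named genes followed a rule: Btaf1; the 12 largest rises and 12 largest falls past the threshold with 1 sign on all 4 arrays; up to 4 members per list, the largest with 1 sign; and 5 per direction for the difference between sets. The samples, comparisons, lists, naming rule and most alternative settings were set before the data were examined; genes named outside the rule are identified as such. Single genes that the rule gives but the text does not name are not reported here, while counts and lists include them.

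On simulated ratios with the spread of the real arrays, the mutant comparison recovered 40 of 50 probes shifted by 0.6 on the log2 scale, and 50 of 50 at each of 1, 1.5 and 2, none in the wrong direction, over 21940 probes. It called 11 unchanged probes, 5.39% of its calls. The difference between sets recovered 44 of 50 probes at a shift of 1 and 50 of 50 at 2. False calls of that test were not counted. A simulated list of 30 genes shifted by 0.4 was called, and 0 of 32 unshifted lists were, over 12895 genes. Simulated genes varied independently of each other. In the data the estimated correlation within lists ran from -0.20 (maternal decidua and blood) to 0.51 (Wnt targets). The simulation therefore does not gauge false calls of lists whose members vary together.

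The alternative settings were the software's processed signals, the deposited value table, no background correction, an offset of 10, median centring in place of loess, Aquantile scaling between arrays, no filter or a stricter one, the 4 arrays as samples with a dye term, an intensity trend in the variance, each array and each set left out, the mean over a gene's probes, an estimated correlation, no dye term between the sets, and another window or size for the flank. A random block for the set with a dye term could not be fitted on 4 arrays; the same block without the dye term was added after seeing the data. Also added then were the tests of lists between the sets and of families of gene symbols. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value.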

Results

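Transcript levels were measured in pools of whole embryos homozygous for V1330M in Btaf1, a missense allele induced by the mutagen ENU, against pools of wild-type embryos. BTAF1 is an ATPase that removes the TATA-binding protein TBP from DNA. There were 4 arrays in 2 groups, with 2 stage_matched and 2 age_matched arrays, and each group was 1 pair of pools hybridised in both dye orientations. Of 43379 spots per array, the share well above background in Cy3 was 57.1% and 56.8% on the stage_matched arrays and 57.8% and 52.9% on the age_matched arrays. In Cy5 it was 56.2%, 59.5%, 59.6% and 57.4% in the same order. No spot was saturated (0 on each array). Values below are log2 ratios of mutant over wild type, given as the mean of the 2 sets with the SD between them (n = 2), and adjusted p values of genes are from limma. That SD leaves out the spread between dye-exchanged arrays of the same pools. Camera p values of lists at the preset correlation weigh members against other genes. However small, they do not measure replication over pools.

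Btaf1 itself was read by 1 probe (A_51_P493602, chromosome 19, 37086826 to 37086885, mm9). Its ratio was 0.28 and -0.12 on the stage_matched arrays and 0.20 and 0.05 on the age_matched arrays. The mean was 0.10 ± 0.03 (SD, n = 2; limma adjusted p = 0.555). The allele exchanges 1 amino acid and removes no transcript sequence, so this level does not check which pools were mutant.

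The first comparison asks which transcripts differ between mutant and wild-type embryos at about the stage when the first somites form. Direct targets of p53 took 7 of the 12 largest rises, led by Ccng1 (cyclin G1) at 3.66-fold. The 12 largest falls held genes of heart muscle, led by Myh7 (a myosin heavy chain) at 3.23-fold lower, genes of the yolk sac endoderm, led by Apoa1 at 3.13-fold lower, and the embryonic globins Hbb-bh1 and Hba-x. By limma, 269 genes were higher and 353 lower, from 365 higher and 690 lower probes, and 598 of these 622 genes had 1 sign on all 4 arrays. The share of called probes that were higher was 34.6%, against 12.7% with median centring in place of loess. Leaving out 1 array leaves its set in 1 dye orientation, where dye bias no longer cancels, so such counts do not weigh that array alone. Calls fell most without array age_matched replicate 1, where limma called 10 probes higher and 13 lower, all 23 of them among the 1055. The count was 150 and 439 without age_matched replicate 2, 183 and 393 without stage_matched replicate 1, and 393 and 814 without stage_matched replicate 2. It was 20 and 42 without background correction, 209 and 386 with no filter on dim probes, and 747 and 1077 with the software's processed signals. Of the 24 genes with the largest changes, Ddit4l, Cdkn1a, Rnf213, Gfra3, Tmem87a, Hbb-bh1, Hba-x, Nppa, Myl2 and Actc1 lost their call without age_matched replicate 1, with 0 reversed; so did every called gene that the rule names outside those 24, which made 55 of 131 named genes.

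The p53 targets rose as a group. Of 32 tested members 31 had positive ratios; 14 rose past the threshold over all genes, 22 when adjusted over the list alone, and none fell (0 past it). The median was 0.38, with 0.33 in the stage_matched set and 0.43 in the age_matched set (limma camera adjusted p = 2.74e-16; adjusted p = 0.732 with an estimated correlation). Ccng1 (probe A_52_P612803, chromosome 11, 40562427 to 40562486) rose by 1.87 ± 0.04, with limma adjusted p = 0.000545 and a positive ratio on 4 of 4 arrays. Its second probe read 1.66. Eda2r, a receptor of the TNF family, rose by 1.74 ± 0.01, and Trp53inp1, a p53-induced nuclear protein, by 1.65 ± 0.04. Single arrays ran from 1.20 to 2.28 for Eda2r and from 1.25 to 2.01 for Trp53inp1. Their second probes rose less, by 0.52 and 0.58. Pmaip1 (NOXA, a killer protein of the BCL2 family) rose by 1.60 ± 0.40 and Cdkn1a (p21, an inhibitor of cyclin-dependent kinases) by 1.20 ± 0.09. Phlda3, an inhibitor of AKT, rose by 1.49 ± 0.43 and Ddit4l, an inhibitor of mTOR, by 1.20 ± 0.04, with 0.87 to 1.57 on single arrays for Ddit4l. Trp53, the gene of p53, is itself in this list and was its 1 member with a negative ratio. It read -0.12 ± 0.48 (limma adjusted p = 0.711) and was named after its value was seen. Among 26 apoptosis genes, which share 5 members with this list, 3 rose, with Pmaip1 and Bbc3 (PUMA, 0.72) among them, the same 3 when adjusted over the list alone. The median of that list was 0.02 (limma camera adjusted p = 0.374). The remaining large rises were Slc19a2, a thiamine transporter, at 1.23 ± 0.17, 4930447C04Rik at 1.23 ± 0.21, Rnf213, a ubiquitin ligase, at 1.19 ± 0.43, Gfra3, a receptor for artemin, at 1.18 ± 0.69, and Tmem87a at 1.14 ± 0.45. A second probe of 4930447C04Rik read 0.48.

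Genes of the visceral endoderm and yolk sac fell as a group. Of 38 tested members 33 had negative ratios and 27 fell past the threshold; adjusted over the list alone, 31 fell and Serpina1d (0.42) was the 1 that rose, named after its value was seen. The median was -0.71, and it was -0.71 in the stage_matched and -0.77 in the age_matched set (limma camera adjusted p = 5.54e-23; adjusted p = 0.732 with an estimated correlation). Apoa1, the main protein of HDL (probe A_51_P408082, chromosome 9, 46037921 to 46037980), fell by 1.64 ± 0.21 with limma adjusted p = 0.000753, negative on 4 of 4 arrays. Slc2a2 (the glucose transporter GLUT2) fell by 1.61 ± 0.12, Rbp4 (the retinol carrier of blood) by 1.49 ± 0.02, and Afp (alpha-fetoprotein) by 1.43 ± 0.03. The second Slc2a2 probe read -0.82. Rbp4 lies on chromosome 19, within 20 Mb of Btaf1.

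Cardiac genes fell as well. Of 35 tested members 33 had negative ratios and 17 fell past the threshold; adjusted over the list alone, 25 fell and Isl1 (0.37), a factor of heart progenitors, was the 1 that rose. The median was -0.51, with -0.27 in the stage_matched and -0.65 in the age_matched set (limma camera adjusted p = 9.42e-14; adjusted p = 0.732 with an estimated correlation). Myh7 (probe A_52_P88033, chromosome 14, 55589526 to 55589585) fell by 1.69 ± 0.35 with limma adjusted p = 0.00148, negative on 4 of 4 arrays. Tnni3 (cardiac troponin I) fell by 1.62 ± 0.47, Nppa (atrial natriuretic peptide) by 1.51 ± 0.89, Myl2 (ventricular myosin light chain) by 1.48 ± 0.57, and Actc1 (cardiac actin) by 1.39 ± 0.64. Gja5, a gap junction protein outside the list, was 2.83-fold lower (SD of the log2 ratio 0.38) at 1 probe and read -0.01 at a second. Among regulators of heart development in the list, Mef2c and Tbx5 read -0.51 and -0.41, Nkx2-5 -0.18, Gata4 -0.09 and Hand2 -0.02, and these 5 and Isl1 were named after their values were seen. Between the same sets the median of the 4 sex-linked genes went from 0.22 to -0.75.

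Of 23 genes of the primitive red cell lineage, 5 fell past the threshold, 8 adjusted over the list alone, with a median of -0.17 (limma camera adjusted p = 0.00257). Among these, the globin Hbb-bh1 fell by 1.64 ± 0.70, Hba-x by 1.57 ± 0.75 and Aqp8, a water channel, by 0.64 ± 0.04. Endothelial genes had a median of -0.20 with 24 of 25 negative; Kdr (VEGF receptor, -0.54) and Gja4 (a gap junction protein, -0.50) fell, and 3 did when adjusted over the list alone (limma camera adjusted p = 1.72e-05). Hypoxia and glycolysis genes had a median of -0.20 over 39 members; Ankrd37 fell (-0.45), and 2 did when adjusted over the list alone (limma camera adjusted p = 2.81e-05). In the neural crest list 4 of 27 fell, 6 adjusted over the list alone, with a median of -0.12 (limma camera adjusted p = 0.00245). Among them were Sox10, a neural crest transcription factor (-1.05 ± 0.51), Crabp1 (-0.57) and Prrx1 (-0.53). With an estimated correlation these 4 lists had adjusted p = 0.732. All 4 kept their call under every other setting that tests lists, but sizes moved. The neural crest median was -0.064 without stage_matched replicate 1, -0.050 without age_matched replicate 1 and -0.22 with median centring. The red cell median was -0.071 with no filter on dim probes and -0.067 with both channels above background. The hypoxia median was -0.12 in the stage_matched and -0.30 in the age_matched set.

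Lists of growth and proteostasis genes had small negative medians. It was -0.14 for 36 S phase genes, with 0 past the threshold and 0 adjusted over the list alone (limma camera adjusted p = 0.0104). For 36 mitosis genes it was -0.09, with 3 falling and 0 rising, and 5 and 2 adjusted over the list alone (limma camera adjusted p = 0.0203). Cenpa, the centromeric histone, fell by 0.67 ± 0.12, Top2a by 0.45 and Ndc80 by 0.43. Of 18 heat shock genes, Hspb1 (-0.52) and Hspa1a (-0.46) fell, the same count of 2 adjusted over the list alone, with a median of -0.13 (limma camera adjusted p = 0.0127). Among 78 ribosomal protein genes, Rpl27a (-0.82) and Rpl31 (-0.59) fell, again 2 adjusted over the list alone, with a median of -0.07 (limma camera adjusted p = 0.0260). In the stage_matched and the age_matched set the medians were -0.11 and -0.083 for S phase, -0.011 and -0.19 for mitosis, -0.10 and -0.19 for heat shock and -0.027 and -0.062 for ribosomal genes. These 4 calls had adjusted p = 0.732 with an estimated correlation and ended with median centring. The ribosomal median turned to 0.09 without stage_matched replicate 2 and to 0.07 without age_matched replicate 2, and the other calls ended without stage_matched replicate 1 (S phase, -0.091), age_matched replicate 1 (S phase, -0.049; mitosis, -0.076) or age_matched replicate 2 (heat shock, -0.21).

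Genes of the primitive streak and of pluripotent cells were higher, with a median of 0.17 over 27 members (limma camera adjusted p = 0.0499; adjusted p = 0.769 with an estimated correlation). Past the threshold 4 rose and 1 fell, and 7 and 2 did when adjusted over the list alone. Fgf5, a growth factor of the epiblast, rose by 1.05 ± 0.52, Mesp1, a factor of early mesoderm, by 0.97 ± 0.67, and Nodal, a signal that patterns the streak, by 0.88 ± 0.42. Tdh, threonine dehydrogenase, fell by 0.86 ± 0.03. The list's median was 0.06 in the stage_matched and 0.28 in the age_matched set, between which the sex-linked median also turned. Wnt targets had a median of 0.13 over 22 members (limma camera adjusted p = 0.0499; adjusted p = 0.769 with an estimated correlation). Over all genes 0 rose and 1 fell, and 3 and 1 when adjusted over the list alone; Apcdd1, a Wnt inhibitor, fell by 0.41. The Wnt median was -0.07 in the stage_matched set and 0.21 in the age_matched set, and neither this call nor that of the streak list held without background correction. The streak median was 0.071 with median centring, where its call held (limma camera adjusted p = 0.000419) and that of the Wnt list (0.033) ended; with processed signals the Wnt median was 0.22. The Wnt call also ended without stage_matched replicate 2 (median 0.10) and without age_matched replicate 2 (0.060).

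The other lists did not pass. Of 27 presomitic mesoderm and somite genes, 6 rose and 1 fell, 7 and 3 adjusted over the list alone, with a median of 0.04 (limma camera adjusted p = 0.126). Tbx6 (0.89 ± 0.52), Dll3 (0.79 ± 0.40), Cer1 (0.73 ± 0.47) and Dll1 (0.56 ± 0.28), which act in the mesoderm that forms somites, were among those that rose. Of 34 neural tube and brain genes, 1 rose and 7 fell, 5 and 8 adjusted over the list alone, with a median of -0.07 (limma camera adjusted p = 0.0917). En2, a midbrain and hindbrain factor, fell by 1.01 ± 0.61, Dbx1 by 0.95 ± 0.14 and Zic1 by 0.81 ± 0.48. Of 14 left-right genes, Nodal and Lefty1 (0.77 ± 0.37) rose, 5 adjusted over the list alone, with a median of 0.19 (limma camera adjusted p = 0.0917). The 5 include Cfap299 (0.37), which entered this list by error through an old symbol meant for Fam183b and is named after its value was seen. For the integrated stress and unfolded protein response, with 43 genes, the median was -0.09 (limma camera adjusted p = 0.0947). Atf5 (0.68) and Hyou1 (0.45), the latter named after its value was seen, rose and Sdf2l1 (-0.54) fell, and 3 rose and 3 fell when adjusted over the list alone. In the stage_matched and the age_matched set the medians were 0.087 and 0.20 for the presomitic, 0.073 and 0.30 for the left-right and -0.036 and -0.13 for the integrated stress list. These 4 lists passed under some other settings: with median centring the left-right and presomitic lists (limma camera adjusted p = 0.0102 and 0.0156), and with no filter on dim probes the neural tube list and the integrated stress list (limma camera adjusted p = 0.0396 for both).

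In the machinery around BTAF1, Tbpl1, a relative of TBP, was the 1 member of 19 TBP regulators past the threshold. It rose by 0.51 ± 0.02 (limma adjusted p = 0.0256), also adjusted over the list alone, while its other probes read 0.22 and 0.16. That list's median was 0.02 (limma camera adjusted p = 0.781). TFIID subunits had 0 of 16 past the threshold either way and a median of 0.03 (limma camera adjusted p = 0.654). In the Pol I and Pol III list Cd3eap, a Pol I subunit, fell by 0.43 and 31 of 32 did not pass; 0 did when adjusted over the list alone (limma camera adjusted p = 0.757). Its median was 0.02, with 0.038 in the stage_matched and -0.017 in the age_matched set, its mean was -0.01, and the test pointed down.

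The remaining tissue lists had medians of 0.06 for gut endoderm and notochord (30 genes, 1 past the threshold and 1 adjusted over the list alone, Pyy at -0.96), 0.05 for trophoblast (15 genes, 0 and 2) and -0.22 for maternal decidua and blood (6 genes, 0 and 0). The limma camera adjusted p values were 0.654, 0.571 and 0.654. The maternal median was -0.040 in the stage_matched and 0.25 in the age_matched set, so that of the set means matches neither, and it was 0.029 with no filter on dim probes. The trophoblast median was -0.040 and 0.062 in the same order. Allantois and extraembryonic mesoderm had -0.08 over 24 genes (limma camera adjusted p = 0.126), where Postn, a matrix protein, fell by 0.91; adjusted over the list alone, 1 rose and 3 fell. Hox genes had 0.06 over 27 genes (limma camera adjusted p = 0.438). Hoxb2 rose by 0.53, and Hoxa9 and Hoxb9 fell by 0.46 and 0.64, Hoxb9 named after its value was seen. In all, 4 rose and 2 fell when adjusted over the list alone. The 4 sex-linked genes had -0.23, with 0 past the threshold either way (limma camera adjusted p = 0.374). This list pools Xist with Y-linked genes that went the other way between the sets, so its median and test mix opposed members.

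Among signalling targets the medians were 0.08 for FGF (17 genes), -0.04 for Hedgehog (15 genes) and -0.04 for BMP (16 genes). Their limma camera adjusted p values were 0.544, 0.552 and 0.374. Phlda1 of the FGF list fell by 0.54 and Nkx6-1 of the Hedgehog list by 0.46, and no BMP target passed (0 of 16). Adjusted over the list alone the counts were 1 higher and 1 lower for FGF, 1 lower for Hedgehog and 0 for BMP. Retinoic acid targets had a median of 0.03, a mean of -0.04 and a test pointing down (22 genes; limma camera adjusted p = 0.571). Nrip1 (-0.49, with 1 of its 2 other probes at 0.03) and Cyp26a1, which degrades retinoic acid (-0.47), fell, and 4 fell when adjusted over the list alone. Cyp26a1 lies on chromosome 19, within 20 Mb of Btaf1. Notch targets had a median and a mean of 0.03 while the test pointed down (16 genes; limma camera adjusted p = 0.817). Dll3 and Dll1 rose and Hes5, a Notch effector, fell by 0.71, with the same 2 and 1 adjusted over the list alone. Medians of 3 of these lists had opposite signs in the stage_matched and the age_matched set: -0.12 and 0.12 for Notch, -0.11 and 0.074 for BMP and -0.089 and 0.036 for retinoic acid targets.

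**Figure D1:**
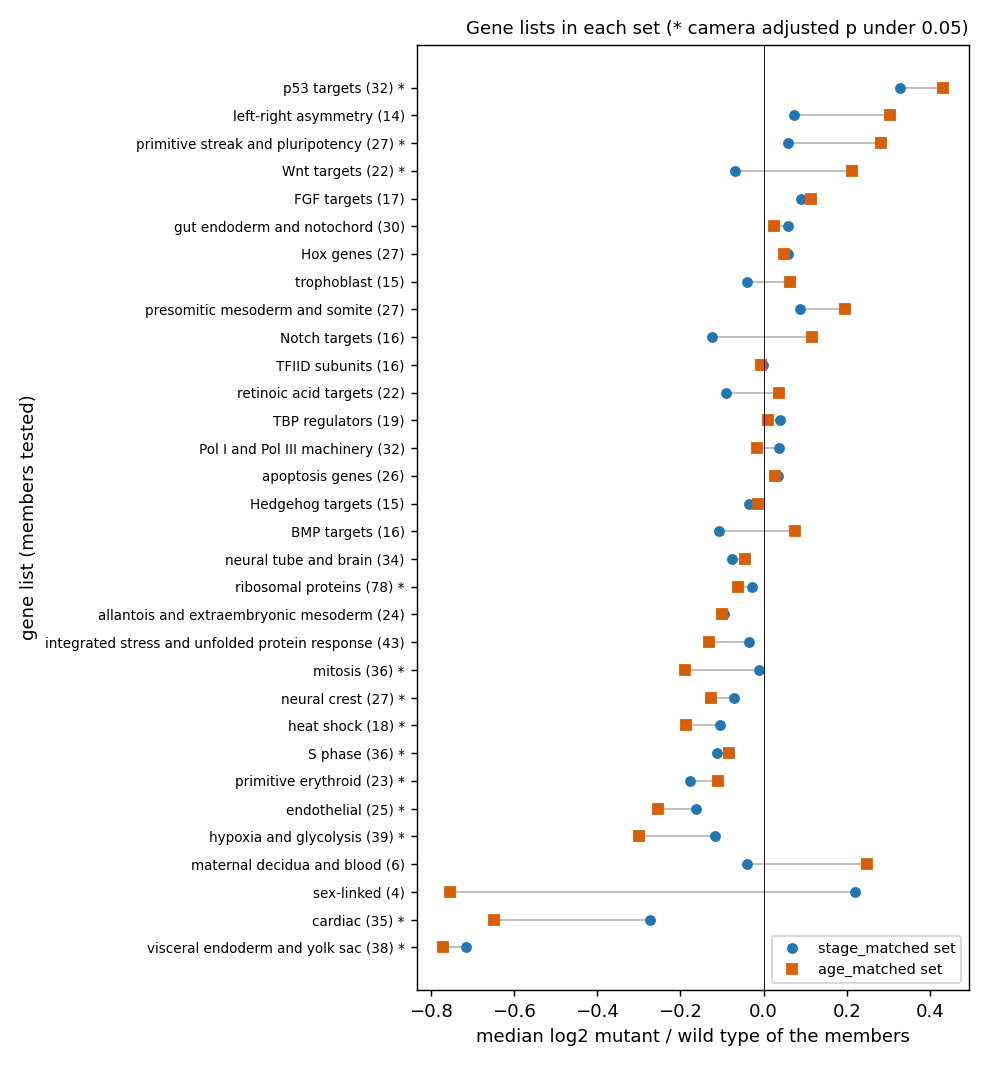
Median log2 ratio of mutant over wild type over the tested members of each fixed gene list (number of members in brackets), with 1 circle for the stage_matched set and 1 square for the age_matched set. Yolk sac genes lie lowest in the age_matched set at -0.77 and at -0.71 in the stage_matched set, and p53 targets lie at 0.43 and 0.33.

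**Figure D2:**
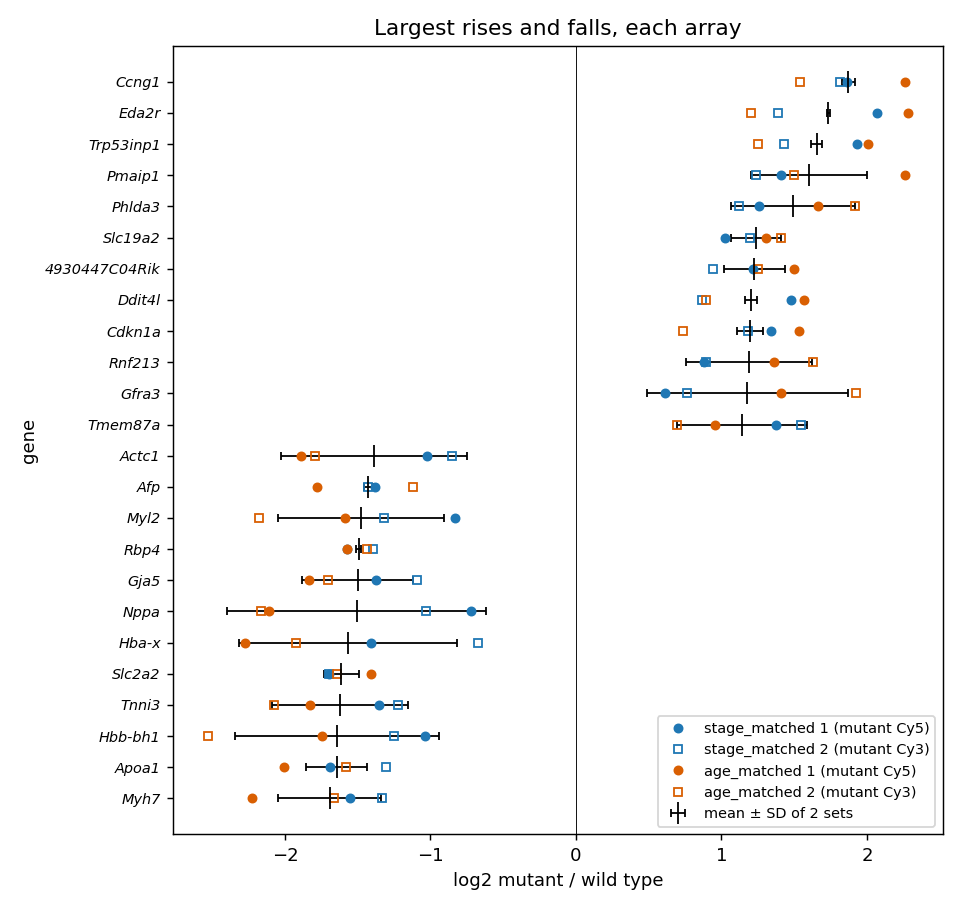
Log2 ratio of mutant over wild type on each of the 4 arrays for the 12 largest rises and the 12 largest falls past the threshold with 1 sign on all arrays. Bars are the mean ± SD of the 2 sets; Ccng1 lies at 1.87 and Myh7 at -1.69.

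Counted without a test, 18 probes were at least 2-fold higher and 43 at least 2-fold lower with 1 sign on all 4 arrays, which is 14 and 35 genes. With the sign of 1 set turned, so that changes shared by the sets cancel, 2 probes met the same criteria against 61. At 1.5-fold there were 116 higher and 323 lower, 439 in all against 9 with the sign turned. As a measure of strong dye bias left after loess, 58 probes were 1.5-fold brighter in 1 dye on all 4 arrays and 0 were 2-fold brighter. Smaller dye bias is not in that count but shows in the correlations below. Without a dye term, the consensus correlation within a set was -0.37. Over all tested probes, which are not independent replicates, mutant over wild-type ratios of arrays from different sets with the same dye orientation were correlated at Pearson r = 0.706 (mutant in Cy5) and 0.423 (mutant in Cy3), while the dye-exchanged arrays of the same pools were at 0.392 in the stage_matched and 0.157 in the age_matched set. Over the 622 genes called from the same arrays all pairs were at 0.774 to 0.912. With the software's processed signals 75 probes were 2-fold higher and 160 lower, with no background correction 10 and 35, the age_matched set alone gave 38 and 70, and the stage_matched set alone gave 17 and 105.

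The second comparison asks whether the difference between mutant and wild type depended on how the pools were matched. Across genes the ratios of the sets were correlated (Pearson r = 0.595, Spearman rho = 0.528, over 12895 genes, which are not independent replicates; r = 0.348 without age_matched replicate 1), and 67.5% of tested probes had 1 sign in both sets. The cardiac and the streak lists moved further in the age_matched set (limma camera adjusted p = 5.29e-21 and 1.67e-09 for the difference; adjusted p = 0.624 with an estimated correlation for both). Nppa read -0.88 in the stage_matched and -2.14 in the age_matched set, Myh6 (a myosin heavy chain) -0.81 and -1.91, and Ankrd1 (a muscle stress protein) -0.36 and -1.51. Mesp1 read 0.50 and 1.44. The single genes Hbb-bh1 (-1.14 and -2.14) and En2 (-0.58 and -1.44) differed too, but no difference was detected for their lists: the medians were -0.18 and -0.11 for primitive red cell genes (limma camera adjusted p = 0.839) and -0.075 and -0.045 for neural tube and brain genes (limma camera adjusted p = 0.864). For yolk sac genes the median difference, stage_matched minus age_matched, was -0.01 over 38 members and none was detected (limma camera adjusted p = 0.776). For p53 targets the median difference was -0.083 over 32 members, and 22 of them were larger in size in the age_matched set. That list did pass (limma camera adjusted p = 0.00416, and 0.624 with an estimated correlation).

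By limma, 272 genes (507 probes) differed between the sets. In 124 of these genes the sets had opposite signs; 96 were higher in the stage_matched and 176 in the age_matched set. Genes that mark sex and maternal tissue were among those with opposite signs. Xist, which is expressed from the inactive X chromosome, read -0.75 and -1.25 on the stage_matched arrays and 0.53 and 1.02 on the age_matched arrays; the mean of 1 of its 3 other probes had the opposite sign. The Y-linked genes Ddx3y and Eif2s3y read 0.41 and 0.33 in the stage_matched set against -0.85 and -0.81 in the age_matched set. Hbb-bt, an adult globin, read -1.35 and 0.91, and Prl8a2, made by the decidua and named after its values were seen, -0.94 and 0.51. Prl4a1, a prolactin-family gene that is in no fixed list and was not assigned to a tissue, read -1.28 and 0.47. Ptprz1 read -1.98 and -0.36, and Grn -1.87 and -0.24, at 1 very bright probe each. Their dye-exchanged arrays differed widely. On the stage_matched and then the age_matched arrays, Ptprz1 read -1.31, -2.65, -0.78 and 0.06, and Grn -1.25, -2.49, -0.88 and 0.41. Other probes of Ptprz1 had means of -0.03 and 0.06 and that of Grn -0.14. Of the 622 genes called in the first comparison 58 also differed between the sets, and 44 of these were larger in size in the age_matched set. Over all 622 called genes, 356 were larger in size in that set. The error here is technical and nearly alike for all named genes, so the test compares these pools and not the ways of matching. No probe passed (0 by limma) without the dye term or without background correction, 1 passed with median centring and 150 with the software's processed signals.

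**Figure D3:**
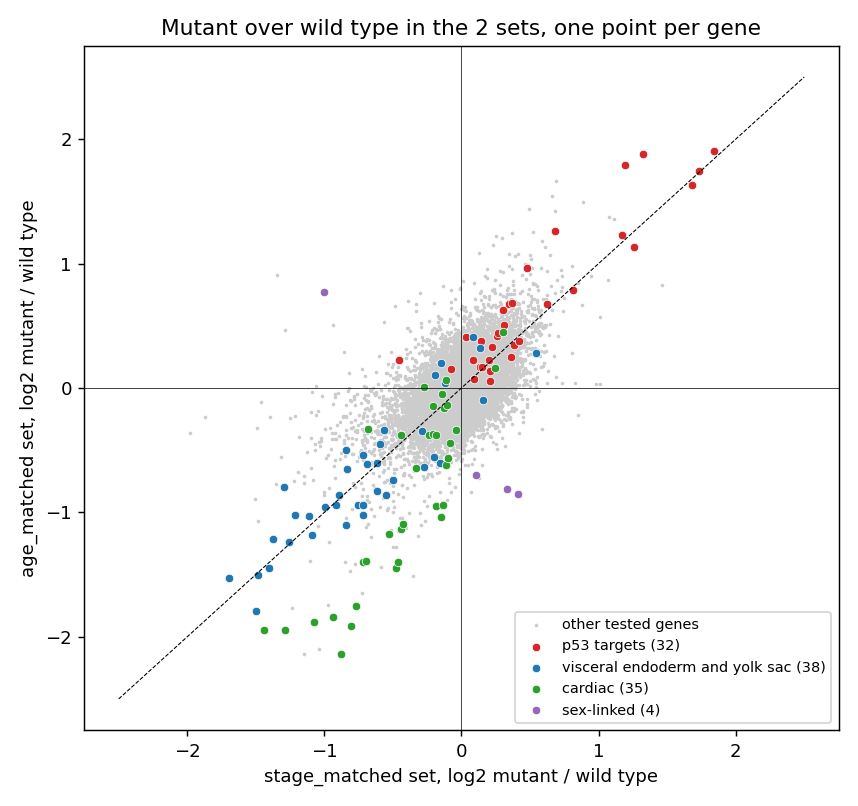
Log2 ratio of mutant over wild type in the stage_matched set (horizontal) and the age_matched set (vertical), 1 point per tested gene, with 4 fixed lists in colour and a dashed line where both sets are equal. Yolk sac genes lie near that line, and p53 targets have medians of 0.33 in the stage_matched and 0.43 in the age_matched set. Cardiac genes lie below the line, with medians of -0.27 and -0.65, and the sex-linked genes lie apart.

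**Figure D4:**
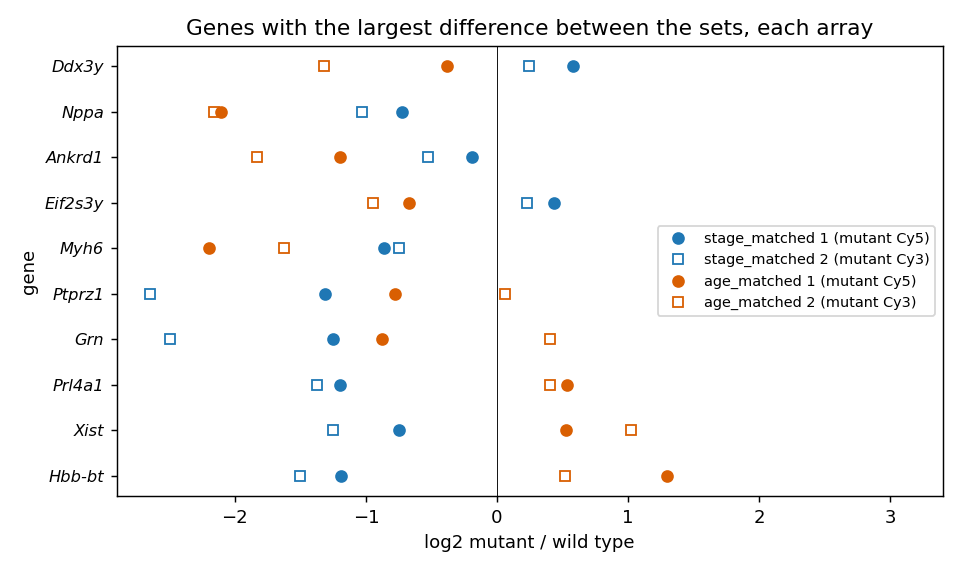
Log2 ratio of mutant over wild type on each of the 4 arrays for the 10 genes with the largest difference between the sets, 5 in each direction. Circles have the mutant in Cy5 and squares in Cy3; Xist, Prl4a1, Hbb-bt, Ddx3y and Eif2s3y lie on opposite sides of 0 in the sets.

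The third comparison asks whether genes near Btaf1 changed more often, since mutants carry C57BL/6J sequence around the mutation and wild-type litter mates can carry FVB/NJ there. Of 218 genes within 20 Mb on chromosome 19, 9 changed at least 1.5-fold with 1 sign on all 4 arrays (4.13%), against 259 of 12668 other genes (2.04%). The odds ratio was 2.06 with an interval of 0.920 to 4.05 (two-sided Fisher's exact test, p = 0.0486). FVB/NJ variants under the probes were not checked, so this count does not separate changes in expression from mismatches at probes. Foxd4 was 2.14-fold higher, and 2700046G09Rik (0.75) and Rln1 (0.59) were higher too. Rbp4 (-1.49), Ankrd1 (-0.93), Mbl2 (-0.93), Sfxn2 (-0.76), Acta2 (-0.59) and Sgms1 (-0.59) were lower; Rbp4 is a yolk sac gene of the fixed list, and Ankrd1 and Acta2 are muscle genes. Tested 1 chromosome at a time, none differed from the rest after adjustment (smallest Benjamini-Hochberg adjusted p = 0.541, Fisher's exact test). The p of the flank was 0.0574 with the software's processed signals, 0.139 without background correction, 0.115 with median centring, 0.103 without stage_matched replicate 2, 0.201 at 2-fold and 0.0147 within 10 Mb (odds ratio 2.65).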

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

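The test of each gene between the sets was planned; the tests of lists between the sets, and the tests that weigh explanations, were chosen after the results were seen. Of 131 named genes, 29 differed between the sets (limma, with terms for set and dye), as did 13 of 32 lists (limma camera). The error for genes is technical and nearly alike for all named ones, and 0 probes passed without the dye term or without background correction. No list passed with an estimated correlation (smallest limma camera adjusted p = 0.624), but with 1 residual degree of freedom hardly any list could. Differences are log2 ratios, stage_matched minus age_matched.

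The first pattern is that p53 targets were higher in mutant embryos. The tables argue against dye bias, since the median over the list was 0.43 with the mutant in Cy3 and 0.44 with the mutant in Cy5. They argue against unequal sex or maternal tissue in the pools as the whole cause, since 30 of the 32 members kept their sign in both sets while Xist, Ddx3y and Hbb-bt turned theirs. A stage gap between mutant and wild-type pools stays open: the stage_matched median was 0.759 of the age_matched one, against 0.421 for cardiac genes, the bootstrap 95% interval over members of that difference, -0.134 to 0.622, includes 0, and the cause of the cardiac difference is itself open. An effect of the mutation itself may account for the rise; no test here separates it from a stage gap.

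The second pattern is that visceral endoderm and yolk sac genes were lower in mutant embryos. A stage gap between mutant and wild-type pools stays open: the stage_matched median was 0.927 of the age_matched one, above the cardiac ratio by a bootstrap 95% interval over members of 0.123 to 0.836, but the cause of the cardiac difference is itself open and each set is 1 pair of pools. A smaller share of yolk sac tissue in the mutant pools may have lowered these genes together, and the labels do not say how much of the yolk sac was kept. The members fell unequally, with an SD of 0.52 over members against a median SD of 0.14 between sets, but members that other tissues also express would fall less, so this explanation and lower expression within the tissue cannot be told apart. Rbp4 and Afp, with mean log2 intensities of 14.0 and 13.7, fell by 1.49 and 1.43.

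The third pattern is that cardiac genes were lower and streak genes higher, both more so in the age_matched set. Array or dye effects are argued against, since the differences were 0.44 and 0.36 for cardiac and -0.32 and -0.35 for streak genes with the mutant in Cy5 and in Cy3, 0.32 in size at the smallest. A wider stage gap in the age_matched set, where up to 5 somites were accepted, is a candidate explanation. The lists taken for that test decided nothing, since the limma camera adjusted p for the difference was 0.365 for neural crest and 0.864 for neural tube genes; presomitic genes were higher in the age_matched set (limma camera adjusted p = 0.00168), but 2 of them are streak genes too and they were not part of the prediction. The wider gap, sex and maternal tissue, which also differed between the sets, and embryo-to-embryo variation cannot be told apart with 1 pair of pools per set.

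The difference was -0.60 for Phlda3, -0.61 for Rnf213, -0.98 for Gfra3 and 0.63 for Tmem87a, all higher in mutants in both sets. Among heart and globin genes it was 1.26 for Nppa, 1.16 for Ankrd1, 1.11 for Myh6, 1.06 for Hba-x, 0.99 for Hbb-bh1, 0.91 for Actc1, 0.87 for Hbb-y, 0.81 for Myl2 and 0.66 for Tnni3. Streak and somite genes had -0.94 for Mesp1, -0.74 for Fgf5, -0.73 for Tbx6, -0.67 for Cer1 and -0.59 for Nodal. Neural genes had 0.86 for En2, 0.72 for Sox10 and 0.68 for Zic1. Genes of sex and maternal tissue had 1.26 for Ddx3y, 1.14 for Eif2s3y, -1.78 for Xist and -2.26 for Hbb-bt. Prl4a1, not assigned to a tissue, had -1.75. Ptprz1 and Grn had -1.62 and -1.64 at 1 probe each. The means of their other probes over both sets were -0.03 and 0.06 for Ptprz1 and -0.14 for Grn.

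For the lists, the median difference was 0.50 for cardiac, -0.34 for primitive streak and pluripotency, -0.13 for presomitic mesoderm and somite, -0.10 for trophoblast, -0.15 for maternal decidua and blood, -0.16 for left-right asymmetry, -0.083 for p53 targets, 0.15 for hypoxia and glycolysis, 0.13 for the integrated stress and unfolded protein response, 0.10 for mitosis, -0.23 for Wnt targets, -0.20 for Notch targets and 0.97 for sex-linked genes. Xist, a member of the sex-linked list, had -1.78, opposite to that median.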

How the results depend on the processing

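The random block without a dye term was chosen after seeing the data; all else was planned, and the planned block with a dye term was not run because it could not be fitted. The cause of each move was not tested, except that a looser filter adds probes to the adjustment and the intensity trend and 4-array fits change the error model. The deposited table and the software's processed signals hold the same ratios and gave the same values. Aquantile scaling left every ratio as it was and says nothing about stability. Signal over background limits which probes were tested (21940 of 41174): the median signal was 152 to 189 in Cy3 and 206 to 221 in Cy5, over median backgrounds of 58.5 to 62.5 and 135 to 136.

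Against 365 higher and 690 lower probes, processed signals and the deposited table gave 747 and 1077, no background correction 20 and 42, an offset of 10 gave 716 and 1274, median centring 120 and 824, no filter 209 and 386, both channels above background 373 and 674, 4 arrays with a dye term 733 and 1216, the random block 1001 and 1575, and an intensity trend 646 and 1229. Leaving out 1 array gave 10 to 393 higher and 13 to 814 lower. It also leaves that set in 1 dye orientation, so dye bias no longer cancels there or in the values below with 1 array left out. The 1055 called probes were compared one by one under the settings for signals, background, offset, centring, scaling, filter and error model and with 1 array left out, and all tested ones kept their direction except 1053 of 1055 without age_matched replicate 1. For 2-fold changes (18 and 43), processed signals and the deposited table gave 75 and 160, no background correction 10 and 35, the age_matched set alone 38 and 70, and the stage_matched set alone 17 and 105. Between the sets (507), processed signals gave 150, median centring 1, and no background correction or no dye term 0. The correlation between sets was 0.348 to 0.580 with 1 array left out. The flank's odds ratio (2.06) was 1.64 with processed signals and with the deposited table, 1.94 without background correction, 1.75 with median centring, 2.49 at 2-fold, 2.65 within 10 Mb, and 1.85 to 2.07 with 1 array left out.

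With an estimated correlation all 13 called lists lost their call at unchanged medians: 0.38 for p53, 0.17 for streak, 0.13 for Wnt, -0.71 for yolk sac, -0.51 for cardiac, -0.20 for endothelial, -0.20 for hypoxia, -0.12 for neural crest, -0.17 for erythroid, -0.14 for S phase, -0.13 for heat shock, -0.088 for mitosis and -0.071 for ribosomal genes. That version has 1 residual degree of freedom, so hardly any list could pass, and the lost calls do not show the effect of correlation alone. For yolk sac genes the estimated correlation was -0.024, under the preset 0.01, yet the unadjusted limma camera p was 0.053, against 1.73e-24. For Wnt, streak and cardiac genes the estimate was 0.51, 0.48 and 0.34, far above the preset. Their unadjusted limma camera p was 0.591, 0.603 and 0.239 with it. Calls of such lists at the preset assume less correlation than was estimated, though 1 residual degree of freedom makes the estimate rough. The p53, yolk sac, cardiac, endothelial, hypoxia, neural crest and erythroid lists kept their call under every other alternative that tests lists. Without background correction the ribosomal (-0.061), streak (0.14) and Wnt (0.099) lists lost theirs. With median centring, which moved the median of all tested probes to -0.074, the ribosomal (-0.071), heat shock (-0.20), S phase (-0.19), mitosis (-0.14) and Wnt (0.033) lists did, and the presomitic list's median turned to -0.00070, still above that of all probes. The Wnt list lost its call with the random block (0.13) and its median turned to -0.070 in the stage_matched set alone. With 1 array left out, medians ran from -0.22 to 0.090 for ribosomal, -0.21 to -0.091 for heat shock, -0.17 to -0.049 for S phase, -0.11 to -0.064 for mitosis and 0.060 to 0.17 for Wnt genes, with calls lost or the sign turned in each. The ribosomal median turned to 0.090 without stage_matched replicate 2 and 0.066 without age_matched replicate 2. Among 131 named genes 0 reversed where called; 55 lost their call without age_matched replicate 1, 50 without background correction, 21 each with no filter and without age_matched replicate 2, 13 and 11 without stage_matched replicates 1 and 2, 4 with median centring, 4 with processed signals and 1 with the random block.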

Other observations

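The groups and genes below were chosen after their values were seen, so no p is given for the histone and H2 groups. Of the 622 genes called by limma, 510 belong to none of the fixed lists. Muscle genes outside the cardiac list were not tested as a group. Single ones that limma called lower were Acta1 (skeletal muscle actin), which fell by 1.36 ± 0.55, Pgam2 (the muscle form of a glycolytic enzyme) by 1.25 ± 0.20, Myl9 by 1.13 ± 0.39, Myom1 (a protein of the sarcomere's M line) by 1.09 ± 0.45 and Myl1 by 0.83 ± 0.44. Cnn1 and Actg2, known from smooth muscle, fell by 0.65 ± 0.32 and 0.61 ± 0.25. Of 225 families of gene symbols with at least 8 tested members, the myosin light chains (Myl) alone passed, with 8 of 10 members lower, 6 of them past the threshold, and a median of -0.79, with -0.51 in the stage_matched and -1.12 in the age_matched set (limma camera adjusted p = 0.00252; adjusted p = 0.994 with an estimated correlation); Myl2, Myl3, Myl4 and Myl7 of this family are also in the cardiac list.

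Of 25 tested genes of the histones made with DNA replication, 7 fell past the threshold and 0 rose, with a median of -0.25, and with -0.36 in the stage_matched and -0.14 in the age_matched set. H1f5 read -1.06 ± 0.41, H4c6 -0.82 ± 0.43, H1f3 -0.76 ± 0.44 and H4c4 -0.73 ± 0.42, while H2ac13, H2ac15 and H2ac18 read 0.39 each and did not pass. Most such transcripts lack poly(A) tails and their sequences are close to each other. Baz1b and Baz1a, subunits of chromatin remodelling complexes, fell by 0.93 ± 0.37 and 0.87 ± 0.32. Of 18 genes of the histocompatibility region named H2, 5 rose and 2 fell, with a median of 0.29, and with 0.30 in the stage_matched and 0.27 in the age_matched set. H2-Bl rose by 0.93 ± 0.03, H2-K1 by 0.71 ± 0.30, H2-K2 by 0.55 ± 0.07, H2-Q2 by 0.53 ± 0.15 and H2-Q10 by 0.41 ± 0.08, and H2-Ab1 and H2-Q1 read -0.70 ± 0.21 and -0.48 ± 0.19. These genes differ in sequence between mouse strains, and the mice were hybrids of 2 strains.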
